A study of Mus musculus with 4 samples.

How the data were processed

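RNA of mammary gland (mice of 6 weeks) and of mammary tumors from Sca-1 knockout and wild-type mice was measured on 4 mouse Affymetrix arrays, 1 per group. Per the labels' protocols, each RNA was pooled from equal amounts of RNA of 5 mice and labelled with biotin by the manufacturer's protocol. The labels attach 1 treatment protocol to all samples, but of the groups' own labels only those of the tumors name the treatment. The deposited values are intensity values, 1 linear signal for each of 22690 probe sets, and the software that made them is not given in the sources used here. Tested on the file, the mean of each array after leaving out its lowest and highest 2% of probe sets was 500, so each array had been scaled to a common trimmed mean. The largest signals were between 11423 and 15092. Lower quartiles were 34.6 and 44.2 in the wild-type and knockout gland and 18.5 and 17.9 in the wild-type and knockout tumor, so the low end of the knockout gland array lay higher than that of the others.

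Values were used as deposited and set on a log scale as log2(signal + 27.3), where the offset is the lower quartile of all values of the 4 arrays. Gene names came from the platform annotation, updated to current symbols by gene identifier, which matched 20364 probe sets. Of 22690 probe sets, 20393 had 1 gene symbol, 691 had several and 1606 were not listed and are unnamed here. The arrays also carry 64 control probe sets, which are part of that total. Probe sets with several symbols were not used. The Sca-1 gene had no probe set named for it in that annotation, and its level is not reported here by name. Each of the 12393 genes was represented by its probe set with the highest mean over the arrays, and 4956 genes had several. A gene was compared where the highest of its 4 values was at or above the median of all values (log2 7.61, a signal of 168), which left 8282 genes. A gene could pass by 1 array alone, so both arrays of a comparison could lie below the floor. This was so for 623 genes in the glands and 1001 in the tumors.

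With 1 array per group no test could be made, and no p-value is given. Genes were counted where a log2 difference was at least 1 in size (2-fold), and for the difference of differences at least 2 (4-fold). As a gauge of measurement noise, the spread between 2 probe sets of the same gene was computed over 2764 genes. It was 0.22 on the log2 scale for the genotype difference in gland, 0.18 in tumor, and 0.52 and 0.47 for tumor against gland in wild type and knockout. Where the first of the 2 probe sets was past 2-fold, the other had the same sign in 94.4% for the gland (17 of 18 genes) and 98.7% for the tumor (74 of 75). For tumor against gland it was 88.5% (586 of 662) in wild type and 91.3% (599 of 656) in knockout. Both probe sets were past 2-fold in size for 10 of the 18 genes in the gland and 36 of the 75 in the tumor. For tumor against gland these numbers were 417 and 427. This spread does not cover differences between mice or pools.

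The analysis used 25 gene lists fixed before the data were examined, for the Ly6 family, cell types of the tissue (white and brown adipocyte, luminal, basal and myoepithelial, keratinising, fibroblast, T and NK, B and plasma, macrophage and neutrophil, endothelial, skeletal muscle and erythrocyte) and processes (PPAR-gamma, TGF-beta and BMP, milk, cell cycle, matrix proteases, interferon response, MHC class II, xenobiotic response, Wnt, EMT, immediate early and control genes). Of their 468 genes, 413 had a named probe set. For each list the median log2 difference is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these arrays, and a list was called outside the central range below 2.5 or above 97.5. The number of lists outside was 12 in the gland, 14 in the tumor, and 18 and 16 for tumor against gland in wild type and knockout.

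The rule for named genes was also fixed before the data were examined. It takes the measured Ly6 family; for each of the 4 comparisons the 10 largest increases and the 10 largest decreases past 2-fold whose other probe sets above the floor had the same sign, without clone, predicted or locus names; the 10 largest differences of the same sign in both tissues each way; up to 4 members of each list with the largest differences; and Gdf10, Pparg, Esr1, Pgr and the control genes. A further gene of the rule is not reported here. Genes named outside this rule were chosen after their values were seen, namely Csn3 in the comparison of the tumors and the genes of the closing section that other lists bring in.

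The procedure was tested on simulated data for the gland comparison, with 7560 genes and noise of 0.2 per array on the log2 scale. Of 50 genes changed 2-fold 22 passed the threshold, of 50 changed 1.5-fold 2, and all 50 changed 4-fold and all 50 changed 8-fold. Of 7360 unchanged genes 3 passed. A changed list reached percentile 100, and 6 of 100 unchanged lists fell outside the central range. The changed genes were drawn only from genes well above the floor, and the noise was independent and of the same size for every gene. Recovery of dim genes, and unchanged lists whose members move together, were therefore not covered.

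Alternatives fixed beforehand were quantile normalization, centring of each array on its median and cyclic loess for the scaling; an offset of 1 and of the pooled median; no floor, a floor on the mean and a floor at the 75th percentile; the mean of all probe sets of a gene; leaving out probe sets whose names mark them as possibly shared between transcripts or genes; a threshold of 4-fold; and random lists without matching. One alternative, the gland counts without genes of salivary and leukocyte lists, was chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used, with R 4.3.3 and limma 3.58.1 for cyclic loess.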

Results

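Gene expression was measured in mammary tissue of female, nulliparous C57BL/6 mice that either lacked Sca-1 (stem cell antigen-1, a cell surface protein used as a marker of stem and progenitor cells) or were wild-type littermates. The 4 groups were mammary gland at 6 weeks of age, wild type and knockout, for which the group labels name no carcinogen, and mammary tumors of mice of both genotypes. The tumors had been induced with 15 mg of MP, a depot progestin, given under the skin, followed by 4 weekly doses of 1 mg of DMBA, a polycyclic hydrocarbon carcinogen, given by mouth. Each group was a pool of RNA from 5 mice on 1 array, so there were no replicates, no test was possible, and a difference below is a difference between 2 arrays. The arrays held 22690 probe sets. Their median signals were 167 in the wild-type gland, 199 in the knockout gland, 151 in the wild-type tumor and 153 in the knockout tumor, and the number of arrays limits the precision. Across all probe sets, which are not independent replicates, Pearson's r was 0.983 between the glands, 0.981 between the tumors and between 0.878 and 0.881 for a gland and a tumor. Fold differences below are on the log2(signal + 27.3) scale, which understates differences of dim genes, and "higher" or "lower" as a count means at least 2-fold. Where 1 signal of a pair is at background, the size of the fold depends on that offset.

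Signs of RNA integrity differed between the arrays. The ratio of the 3' to the 5' control probe set of beta-actin was 2.35 in the wild-type gland, 1.61 in the knockout gland, 1.23 in the wild-type tumor and 1.29 in the knockout tumor. The corresponding ratio for Gapdh was 1.72, 0.988, 0.768 and 0.876. Of the 12 control genes fixed in advance, 9 were measured. Their median log2 difference between genotypes was -0.01 in the gland, where its sign turned under quantile normalization and cyclic loess, and -0.02 in the tumor. Actb itself was not steady, with signals of 1318 and 2578 in the wild-type and knockout gland and 10053 and 9895 in the wild-type and knockout tumor. Its probe sets disagreed in the gland, where the log2 difference of 0.95 turned to -0.30 without shared probe sets and the 3' control probe set had signals of 3803 and 4238.

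No probe set was named for the Sca-1 gene in the annotation used, so the knockout was not checked by gene name here. Sca-1 belongs to the Ly6 family of small, mostly membrane-anchored proteins, and 3 other members were bright enough to be compared. Lynx1, a modulator of nicotinic receptors, was 1.70-fold lower in the knockout gland and 1.89-fold lower in the knockout tumor, where both signals, 131 and 56.7, were below the floor. Ly6d was 1.86-fold lower in the knockout gland (signals 3679 and 1965) and differed by 0.21 on the log2 scale in the tumor. Cd59a, an inhibitor of complement, differed by -0.06 in the gland and was 1.76-fold lower in the knockout tumor. The family median was -0.76 in the gland and -0.82 in the tumor, with no member past 2-fold in either tissue. When dim members were included, the gland median turned to 0.12 and the tumor median shrank to -0.02.

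In the mammary gland, the comparison of genotypes asks what differed with the loss of Sca-1 in tissue without a tumor. By list medians, the knockout gland had higher levels of lymphocyte genes, above all those of B cells, and of genes of dividing cells, and lower levels of brown fat genes. Outside the B cell list, most members of these lists differed by less than 2-fold. A set of secretory proteins known from saliva was bright in the wild-type gland and close to background in the knockout gland. Of 8282 genes above the floor, 92 were higher and 21 were lower in the knockout gland, of which 16 and 1 were below the floor in both glands and passed it through a tumor. With the arrays brought to a common median instead, the counts were 44 and 39, and the ratio of higher to lower genes therefore depended on the scaling. The 3' to 5' ratios of the control probe sets were also higher in the wild-type gland, and whether this bears on the counts or list medians was not tested.

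B and plasma cell genes stood out most. Of 14 measured members, 11 were higher, none was lower and 3 lay within 2-fold, with a median log2 difference of 1.32 at percentile 100 of matched random lists. Fcer2a, the low-affinity IgE receptor, was 3.12-fold higher, the B cell kinase Blk 2.92-fold, the inhibitory receptor Cd22 2.75-fold and the immunoglobulin mu chain Ighm 2.75-fold, its signal being 916 in the wild-type and 2569 in the knockout gland. Among the largest single increases were also the immunoglobulin genes Ighg3, 5.96-fold higher, and Iglv1, 5.00-fold higher, and Cxcl13, a chemokine that attracts B cells, 4.27-fold higher. T and NK cell genes had a median of 0.73 (percentile 100), with 1 of 12 members past 2-fold, the T cell coreceptor Cd8a at 2.47-fold, and all 12 positive in sign. Most of the 12, Cd8a included, reached the floor on the knockout gland array alone, as did some B cell genes such as Fcer2a and Blk. The filter itself favoured positive signs for these. Over the alternatives the median ranged from 0.47 to 0.84 for T and NK cell genes and from 0.93 to 1.42 for B cell genes. MHC class II genes had a median of 0.38 (percentile 99.9). Of 7 members, 2 were higher, H2-DMb2 at 2.25-fold and H2-Oa at 2.16-fold, and 5 lay within 2-fold.

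Macrophage and neutrophil genes had a median of 0.42 (percentile 100), with 3 of 21 members higher and none lower. The 3 were the arginine-degrading enzyme Arg1, 4.81-fold higher, and the neutrophil calcium-binding proteins S100a9 and S100a8, 3.35-fold and 3.30-fold higher. Marco, a scavenger receptor of macrophages, was 4.94-fold higher. Glycam1, a mucin-like protein of milk that is also made by high endothelial venules of lymph nodes, was 4.06-fold higher, with signals of 1091 and 4514. The ribosomal protein gene Rps27, also among the 10 largest increases, was 3.23-fold higher, with signals of 124 and 462.

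Cell cycle genes lay higher in the knockout gland as a group, most by less than 2-fold. All 27 measured members were positive in sign, 1 was past 2-fold, and the median was 0.66 (percentile 100). Mcm5, part of the helicase that opens DNA for replication, was 2.36-fold higher, the spindle checkpoint kinase Bub1 1.98-fold, the proliferation marker Mki67 1.98-fold and the mitotic kinase Plk1 1.96-fold. Of the 27 members, 12 were below the floor in both glands, among them Mcm5 (signals 54.5 and 166), Bub1 and Plk1, so their single fold values are uncertain. The leukocyte genes above lay higher on the same array.

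The secretory genes with large decreases are known mainly from salivary and other exocrine glands. Smr3a, a submandibular secretory protein, had a signal of 4808 in the wild-type gland and 1.4 in the knockout gland, 168-fold lower. The antimicrobial protein Bpifa2 was 142-fold lower (7706 and 27.0), the chitinase Chia1 87.3-fold, the nuclease Dnase1 77.4-fold, the secreted carbonic anhydrase Car6 76.8-fold, the prolactin-induced protein Pip 64.8-fold and the cystatin Cst10 44.1-fold. The secretoglobins Scgb2b27 and Scgb1b27 were 7.11-fold and 4.90-fold lower, and Dcpp3 was 5.73-fold lower. The knockout signals were at or near background, so these folds and their order depend on the offset. The log2 difference of Smr3a, -7.40, was -10.97 with an offset of 1 and -4.88 with the pooled median as offset. Most of these genes were also dim in both tumors. Bpifa2, for example, had signals of 1.2 in the wild-type and 7.0 in the knockout tumor.

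Brown adipocyte genes had a median of -0.74 in the gland (percentile 0), with 2 of 7 members lower and 5 within 2-fold. Ucp1, the uncoupling protein that makes brown fat produce heat, was 3.72-fold lower, with signals of 754 and 183, and the lipid droplet protein Cidea was 2.19-fold lower. White adipocyte genes (20 measured) and PPAR-gamma with its targets (15 measured) had no member past 2-fold, with medians of -0.06, of unsettled sign under quantile normalization, and -0.09. Pparg, the nuclear receptor that drives fat cell differentiation, was 1.39-fold lower. Skeletal muscle genes were among the brightest in both glands and differed little between them, with 16 of 16 members within 2-fold and a median of -0.06, which quantile normalization turned to 0.02. Myh4, a fast myosin heavy chain, had signals of 7347 and 7172.

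Fibroblast and extracellular matrix genes had a median of 0.29 (percentile 100), with all 23 members within 2-fold. The matrix glycoprotein Tnc was 1.65-fold higher and the collagen gene Col5a1 1.54-fold. TGF-beta and BMP genes had a median of 0.19 (percentile 99.3), which turned to -0.04 under median centring. Of 24 members 2 were higher, the co-receptor Tgfbr3 at 2.98-fold and, below the floor in both glands, the activin subunit Inhba at 2.43-fold, and 22 lay within 2-fold. Gdf10, a BMP-like growth factor, was 1.36-fold higher. Medians of interferon response genes (0.16), immediate early genes (0.21) and basal and myoepithelial genes (0.13) were above the central range of random lists, with no member past 2-fold. They turned negative under median centring, which moved the median of all genes to -0.21, but stayed above that median.

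The other lists lay inside the central range of random lists in the gland. Luminal epithelium and hormone response genes had a median of -0.08, which cyclic loess turned to 0.05. Of 17 members 1 was higher, the cytokine RANKL, Tnfsf11, at 2.62-fold but below the floor in both glands, and 1 was lower, the pioneer transcription factor Foxa1 at 2.27-fold. Keratinisation genes had a median of 0.04, negative under each of the other scalings, with Krt6a at 3.47-fold and the crosslinking enzyme Tgm1 at 2.55-fold higher among 16 members, 12 of them below the floor in both glands. Milk genes had a median of 0.23, with 2 of 9 members higher, Glycam1 and, below the floor in both glands, the casein Csn1s1 at 2.04-fold. Matrix proteases (median 0.17), xenobiotic response genes (0.12), endothelial genes (0.20), Wnt signalling genes (0.24) and EMT factors (0.20) had no member past 2-fold. Except for the Wnt list these medians turned negative under median centring, which moved the median of all genes to -0.21. The erythrocyte list had 1 measured member, Alas2, which differed by -0.14.

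In the tumors, the comparison of genotypes asks how tumors that arose without Sca-1 differed from those of wild-type mice. Genes of keratinising squamous epithelium were far lower in the knockout tumor, and genes of cell division and 3 of 9 milk genes were higher. Of 8282 genes, 176 were higher and 161 were lower in the knockout tumor, of which 18 and 19 were below the floor in both tumors. List medians of connective tissue, macrophage and neutrophil, and MHC class II genes were modestly lower, though members of the connective tissue list went both ways.

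Of 16 keratinisation genes, 11 were lower, none was higher and 5 lay within 2-fold, with a median of -2.89 (percentile 0). Krt1, the keratin of suprabasal epidermis, was 23.6-fold lower, with signals of 894 and 11.7. The cysteine protease inhibitor Stfa3 was 20.9-fold lower, the keratinocyte protein Krtdap 12.9-fold and Krt6b, a keratin of hyperproliferative epidermis, 12.5-fold. Other large decreases had the same kind of members. Calm4, a calmodulin-like protein of skin, was 54.6-fold lower (2625 and 21.3), the cornified envelope proteins Rptn, Lce1f and Sprr1b were 21.1-fold, 14.9-fold and 11.6-fold lower, and the hair follicle keratin Krt25 11.3-fold. The probe sets of Rptn disagreed. With an offset of 1 another one, with signals of 11.5 and 8.1, stood for the gene, and the log2 difference of Rptn was then -0.46 in place of -4.40. Scgb1a1, a secretoglobin of airway epithelium, was 23.4-fold lower. Most of the 11 lower members of the list reached the floor on the wild-type tumor array alone, so the filter itself favoured lower values in knockout. Where the floor was set on the mean over the arrays, which drops genes bright on 1 array, the list median was -0.58.

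Cell cycle genes went the other way. Of 27 members, 18 were higher and none was lower, all 27 were positive in sign, and the median was 1.13 (percentile 100). Bub1 was 3.19-fold higher, Mcm5 2.87-fold, the ribonucleotide reductase subunit Rrm2 2.81-fold and the cyclin Ccna2 2.68-fold. Some members, Bub1 and Mcm5 among them, reached the floor on the knockout tumor array alone, which favoured higher values for them. Mki67 had signals of 592 in the wild-type and 1204 in the knockout tumor. Milk genes had a median of 0.27 (percentile 98.7), with 3 of 9 members higher and none lower. The casein Csn2 was 6.92-fold higher (231 and 1758) and Glycam1 12.4-fold higher. Csn1s2a, another casein, was 32.1-fold higher by its brightest probe set, but its difference was -0.09 when probe sets that may be shared between transcripts were left out, and the list median was then -0.03. Csn3, a casein bright in both tumors, differed by -0.03.

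Of 16 skeletal muscle genes, 13 were below the floor in both tumors and passed it only through the glands. Their median of 0.62 (percentile 100), with 4 past 2-fold, therefore mostly compares background values and is not read as a difference. The troponin Tnnc2, for example, had signals of 3.3 and 66.7. The skeletal actin Acta1, above the floor in the knockout tumor, was 2.43-fold higher, at 160 and 428. Actc1, the cardiac actin, was 11.4-fold higher. Other single genes with large increases were Erdr1 at 13.1-fold, the secreted neuronal guidance protein Reln at 6.63-fold, the mesothelial surface protein Msln at 6.27-fold, the macrophage protein Cd5l at 6.14-fold, the protease inhibitor Serpinb1a at 6.05-fold and Prp2 at 6.33-fold.

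Fibroblast and extracellular matrix genes had a median of -0.40 (percentile 0), although members went both ways, with 4 of 23 higher and 5 lower. Eln, the elastic fibre protein, was 3.93-fold lower and the gelatinase Mmp2 2.58-fold lower, while Tnc was 3.25-fold and fibronectin, Fn1, 3.02-fold higher. Matrix proteases had a median of -0.64 (percentile 0.02). Of 8 members 3 were lower, the collagenase Mmp13 at 2.45-fold, the stromelysin Mmp3 at 2.18-fold and the macrophage elastase Mmp12 at 2.09-fold, and 1 was higher, the urokinase Plau at 2.72-fold. Macrophage and neutrophil genes had a median of -0.36 (percentile 0), with S100a9 and S100a8 3.80-fold and 2.89-fold lower and the chemokine Ccl2 2.16-fold higher among 21 members. MHC class II genes had a median of -0.43 (percentile 0.08), with all 7 members negative and within 2-fold. Endothelial genes had a median of -0.27 (percentile 0.28), with 14 of 14 within 2-fold. EMT factors had a median of -0.30 (percentile 0.28), with 1 of 11 lower, the transcription factor Zeb1 at 3.38-fold.

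Among signalling lists, Wnt genes had a median of 0.44 (percentile 100), with 2 of 16 higher, the stem cell receptor Lgr5 at 3.72-fold and the ligand Wnt10a at 2.05-fold. TGF-beta and BMP genes had a median of 0.02, of unsettled sign between scalings, with 1 of 24 lower. That member was Gdf10, 4.15-fold lower, with signals of 164 and 18.8, both below the floor. PPAR-gamma and its targets had a median of -0.14 (percentile 5.14), with 1 of 15 lower, the lipase inhibitor Angptl4 at 3.63-fold, and Pparg itself differed by 0.18. White adipocyte genes had a median of 0.19 (percentile 99.7), with Plin4, which coats lipid droplets, 2.76-fold lower and the carbonic anhydrase Car3 2.19-fold higher among 20. Interferon response genes had a median of 0.22 (percentile 99.9) and no member past 2-fold.

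The other lists lay inside the central range in the tumor. B and plasma cell genes had a median of 0.24, with 1 of 14 higher, the immunoglobulin joining chain Jchain at 3.29-fold. T and NK cell genes had a median of 0.16 and no member past 2-fold. In both tumors 9 of 14 and 11 of 12 members of these lists were below the floor, as were 6 of 7 brown adipocyte genes. Luminal genes had a median of 0.11, with Tnfsf11 2.32-fold higher among 17. Basal and myoepithelial genes had a median of 0.12. Of 12 members 2 were higher, Krt17 at 2.42-fold and the smooth muscle actin Actg2 at 2.07-fold, and 2 were lower, the smooth muscle myosin Myh11 at 2.60-fold and calponin, Cnn1, at 2.28-fold. Xenobiotic response genes had a median of -0.14, with sulfiredoxin, Srxn1, 3.63-fold lower among 14. Immediate early genes (median 0.15) and brown adipocyte genes (0.41) had no member past 2-fold, and Alas2 of the erythrocyte list differed by 0.43. The estrogen receptor gene Esr1 and the progesterone receptor gene Pgr were below the floor on every array.

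**Figure D1:**
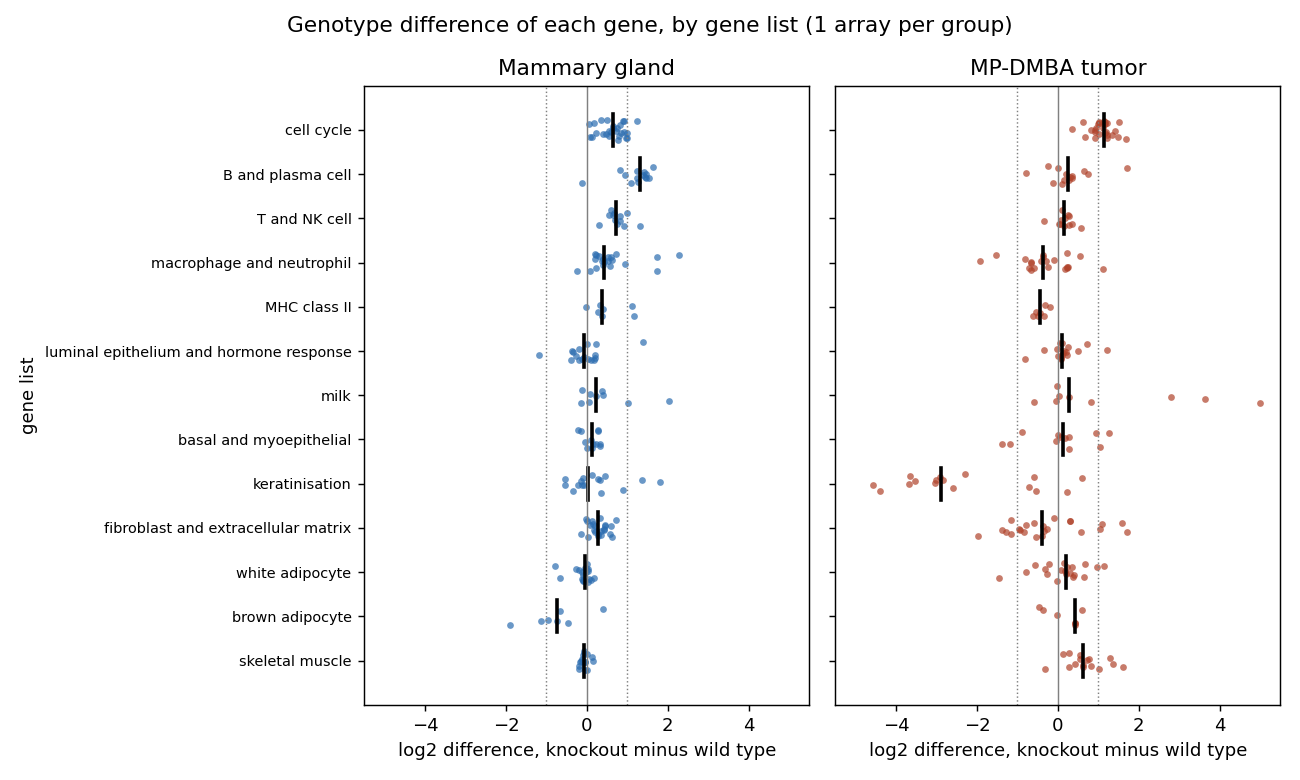
Log2 difference (knockout minus wild type) of each measured gene of 13 lists, in mammary gland (left) and MP-DMBA tumor (right); each point is a gene, black bars are list medians, dotted lines mark 2-fold, and points are spread vertically only to separate them. B and plasma cell genes sit right of 0 in the gland (median 1.32), keratinisation genes left of 0 in the tumor (median -2.89), and cell cycle genes right of 0 in both.

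Across both tissues, 12 genes were higher in the knockout and 1 was lower, where 1.96 and 0.408 would be shared by independent lists of the same sizes. The comparisons of the 2 tissues share no array. The shared increases named by rule were immunoglobulin genes (Ighg3, Iglv1 and Igkv8-30), the B lineage transcription factor Spib at 2.93-fold in gland and 4.43-fold in tumor, genes of replicating cells (Mcm5, Dtl at 2.18-fold and 2.23-fold, and the mitotic kinase Melk at 2.14-fold and 2.09-fold), Tnfsf11, Serpinb1a and Glycam1. Of these, Mcm5, Dtl, Melk and Tnfsf11 were below the floor in both glands and Ighg3 and Iglv1 in both tumors, so their sharing is uncertain. The shared decrease was Scgb2b27, 7.11-fold in the gland and 4.07-fold in the tumor. Next in order were Mmd2, 1.99-fold and 6.05-fold lower, Lynx1, and the zinc transporter Slc39a8, 1.70-fold and 2.20-fold lower. Over all genes above the floor, genotype differences in gland and tumor were nearly unrelated (Pearson's r = 0.018, Spearman's rho = 0.028 across genes, which are not independent replicates). Of the genes past 2-fold in both tissues, 4 were higher in the gland and lower in the tumor, where 1.79 would be shared by independent lists, and 3 went the other way, against 0.446.

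**Figure D2:**
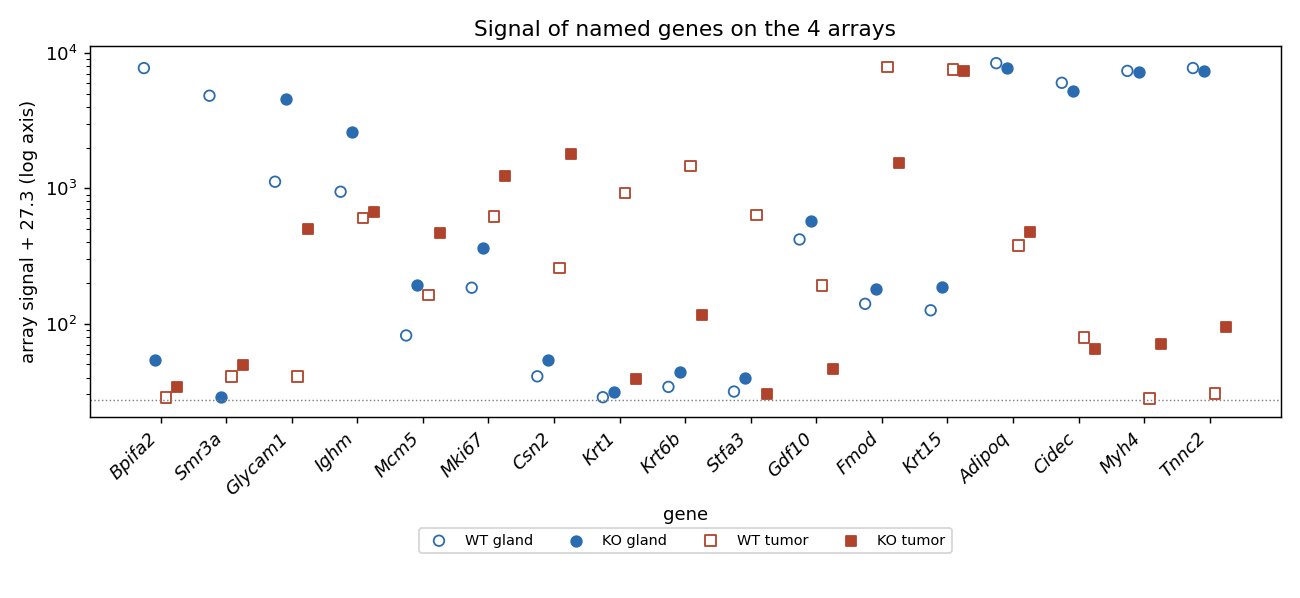
Array signal + 27.3 (log axis) of 17 genes in the 4 groups, 1 array each: circles are glands, squares tumors, open symbols wild type and filled symbols knockout, and the dotted line marks a signal of 0. Bpifa2 and Smr3a stand above the dotted line by a wide margin in the wild-type gland alone (signals 7706 and 4808), and Krt1, Krt6b and Stfa3 do so mainly in the wild-type tumor.

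Tumors were compared with glands of the same genotype to describe what set tumor tissue apart. Tissue and treatment differed together in these comparisons, and the age of the mice with tumors is not given in the sources used here, so none of these can be separated. Both tumors had far less signal from muscle and fat genes than the glands, and more from epithelial keratins, cell cycle genes and macrophage and neutrophil genes. In wild-type mice 1065 genes were higher and 1374 lower in tumor than in gland, and in knockout mice 1023 were higher and 1479 lower. Under median centring the knockout counts became 1696 higher and 1035 lower. The beta-actin control probe sets had 3' to middle ratios of 4.29 and 2.89 in the wild-type and knockout gland, against 1.15 and 1.23 in the tumors.

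Of the lists, skeletal muscle and white adipocyte genes had the lowest medians. In wild-type mice 16 of 16 skeletal muscle genes were lower in the tumor (median -6.68), and in knockout mice 15 of 16 (median -6.08). Myh4 was 264-fold lower in wild type and 101-fold lower in knockout, and the calcium buffer Pvalb 191-fold and 117-fold lower. Their tumor signals were at background (Myh4 0.6 and 44.0, Pvalb 4.6 and 21.7), so the sizes of these folds depend on the offset and are not compared between genotypes. For Myh4 in wild type, the log2 difference of -8.05 ranged from -12.17 to -5.48 over the alternatives. Of 20 white adipocyte genes 19 were lower in each genotype, with medians of -4.01 and -3.56. Pck1, which feeds glycerol synthesis in fat cells, was 94.6-fold and 82.3-fold lower, and the lipid droplet protein Cidec 76.5-fold and 80.0-fold lower. Brown adipocyte genes had medians of -3.36 and -2.19, with 6 and 5 of 7 members lower. PPAR-gamma and its targets had medians of -1.96 and -2.56, with 10 and 11 of 15 lower, Pparg being 20.7-fold lower in wild type and 13.2-fold lower in knockout. Endothelial genes had medians of -1.20 and -1.71, with 8 and 13 of 14 lower, among them the receptor Tek, 7.87-fold and 7.06-fold.

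Basal and luminal epithelial genes were higher by list median. Basal and myoepithelial genes had medians of 2.18 in wild type and 1.76 in knockout, with 9 of 12 higher and 1 lower in each. The basal keratins Krt5 and Krt14 were 9.05-fold and 6.98-fold higher in wild type and 9.98-fold and 9.29-fold higher in knockout, and Krt15, another basal keratin, 60.3-fold and 39.6-fold. Luminal genes had medians of 0.80 and 1.31, with 7 and 11 of 17 higher, including Tnfsf11 and the claudins Cldn3 and Cldn7. Milk genes had medians of 0.82 and 1.79, with log2 differences of 4.02 and 3.81 for the casein Csn1s1, and Glycam1 27.6-fold and 9.01-fold lower. Keratinisation genes differed between the genotypes. In wild type 15 of 16 were higher in the tumor (median 3.41). In knockout 6 were higher and 2 lower (median 0.30, percentile 93.0). Most of the 16 reached the floor on the wild-type tumor array alone, so the filter itself favoured this contrast. Over the alternatives the median ranged from 1.71 to 4.69 in wild type and from -0.04 to 1.62 in knockout. Cell cycle genes had medians of 1.57 and 1.87, with 20 and 22 of 27 higher and 1 lower in each. The ubiquitin-conjugating enzyme Ube2c, which drives exit from mitosis, was 7.81-fold and 11.7-fold higher.

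Saa1, an acute-phase protein, was 73.2-fold higher in the wild-type tumor and 53.7-fold higher in the knockout tumor, the fibrinogen chain Fgb 64.4-fold and 30.6-fold, and the growth factor binding protein Igfbp2 34.9-fold and 23.6-fold. Fmod, a collagen-binding proteoglycan, was 56.2-fold higher in the wild-type tumor and 8.54-fold higher in the knockout tumor. The neuropeptide Nmu was 5.73-fold higher in the wild-type tumor and 34.6-fold higher in the knockout tumor, and the glutathione peroxidase Gpx2 24.4-fold and 32.6-fold. Macrophage and neutrophil genes had medians of 1.73 and 0.69, with 16 and 9 of 21 higher. Arg1 was 29.5-fold and 7.27-fold higher. Matrix proteases had medians of 1.26 and 1.03, with Mmp13 31.4-fold and 13.0-fold higher. Interferon response genes had medians of 0.93 and 0.88, with 9 and 10 of 22 higher. MHC class II genes had medians of 0.68 and 0.25, both inside the central range, and in knockout the latter turned to -0.06 under cyclic loess. B and plasma cell genes had medians of -1.67 and -3.20 (percentiles 0.13 and 0), with 11 and 12 of 14 lower, Ms4a1, the B cell antigen CD20, being 10.1-fold and 21.5-fold lower. T and NK cell genes had medians of -1.20 and -1.78, with 8 and 11 of 12 lower, at percentile 7.72 in wild type, inside the central range of random lists, and 1.80 in knockout.

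Fibroblast and extracellular matrix genes had medians of -0.65 and -1.07, with 9 and 13 of 23 lower and 1 higher in each. Dpt, a matrix protein of connective tissue, was 12.9-fold and 22.1-fold lower. Wnt signalling genes had medians of 0.65 and 0.97, with log2 differences of 4.08 and 3.32 for the secreted inhibitor Sfrp1, and with Sfrp4 10.1-fold and 6.45-fold lower. EMT factors had medians of 0.60 and -0.31, the latter inside the central range and turning to 0.02 under median centring. TGF-beta and BMP genes had medians of 0.20 and 0.12, both inside the central range, with Inhba 8.16-fold higher in wild type and Gdf10 12.4-fold lower in knockout. Xenobiotic response genes had medians of 0.81 and -0.02, the latter inside the central range and of unsettled sign, with the glutathione synthesis enzyme Gclm 6.97-fold and 5.11-fold higher and the glutathione transferase Gstm1 4.94-fold and 7.23-fold lower. Immediate early genes had medians of 0.21 and 0.29, control genes of 0.25 and 0.51, and the Ly6 family of -0.05 and -0.81. The Ly6 medians were of unsettled sign, ranging over the alternatives from -0.07 to 0.32 in wild type and from -0.83 to 0.45 in knockout. Alas2 of the erythrocyte list was 4.88-fold and 3.30-fold lower. These last 4 lists lay inside the central range in both genotypes.

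The genotypes had many of these tumor differences in common, with 762 genes higher in both and 1112 lower in both, where 132 and 245 would be shared by independent lists. These comparisons share no array, and Pearson's r across genes was 0.883. The difference of the differences was at least 4-fold toward higher in knockout for 31 genes and toward lower for 56. As lists, keratinisation (-3.03), B and plasma cell (-1.14), macrophage and neutrophil (-0.80), MHC class II (-0.83), and fibroblast and extracellular matrix genes (-0.78) had medians of this difference below those of random lists (percentile 0), and brown adipocyte (1.07), skeletal muscle (0.74) and cell cycle genes (0.45) above (percentile 100). In both tumors 6 of 7 brown adipocyte, 13 of 16 skeletal muscle and 9 of 14 B and plasma cell genes were below the floor, so these 3 values give no genotype difference among the tumors. The brown adipocyte and B cell values mostly repeat the gland difference with its sign turned. Most keratinisation genes reached the floor on the wild-type tumor array alone, which favoured a low value for that list.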

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

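The tests of array scaling, of the low end of the knockout gland array and of the share of epithelial cells were chosen only after the result was seen. Those of salivary tissue, lymph node tissue, hair follicle skin and squamous differentiation were written down before their gene lists were looked at, though the patterns they bear on had been seen.

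A set of secretory genes of saliva was bright in the wild-type gland and near background in the knockout gland. Array scaling cannot account for this, since the smallest of the 7 large differences still had a size of 5.62 on the log2 scale after quantile normalization. Salivary tissue taken with the wild-type pool may be the source, but the list of other salivary genes did not settle it. Its median of 0.18 over 9 measured members lay above the bound set in advance for excluding it, yet 5 of the 9 were brighter in both tumors than in both glands. That count was taken only after the median was seen. Signal for these 5 need not come from salivary cells, so the median is a weak guide to such tissue. Members went both ways in the knockout gland. Amy1 differed by -0.93 on the log2 scale but stayed bright in the knockout gland. Its signals were 6071.5 and 3176.5 in the wild-type and knockout gland and 32.9 and 37.3 in the wild-type and knockout tumor. By contrast, Cd44 differed by 0.78 and Kcnn4 by 0.54, both among these 5. Outside these 5, Fxyd2 differed by -0.22, Creb3l1 by 0.31 and Tcn2 by 0.24. Below the floor, Lpo differed by -1.67, with signals of 89.6 and 9.4 in the wild-type and knockout gland. Klk1 differed by -1.11 (140.6 and 50.4) and Dcpp1 by -0.84 (52.6 and 17.2), while Spdef differed by 0.24 (95.1 and 117.6). Lman1l differed by 0.83 (1.9 and 24.5) and Oit1 by 0.61 (6.1 and 23.7). Their signals lay below the lower quartile of each gland array, so these increases compare background values. All 24 named members had a median of 0.05. Salivary tissue and a genotype effect cannot be told apart with 1 pool per group.

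B cell genes were higher in the knockout gland. A higher low end of that array was excluded as the whole cause, since the list stayed at percentile 100 of random lists after quantile normalization, with a median of 1.24. Lymph node tissue in the knockout pool is a candidate explanation, since 15 of 15 other leukocyte and lymph node genes were higher in sign, with a median of 0.72. Of these, Cxcr5, Rhoh and Cd27 reached the floor on the knockout gland array alone, which favoured a positive sign. All 17 named genes together had a median of 0.72. Cxcr5, a receptor of follicular B cells, differed by 1.21 and Il7r, a receptor of lymphocytes, by 1.26. Genes tied to lymph nodes varied. The cytokine Ltb differed by 0.72, the homing receptor Ccr7 by 0.26 and, below the floor, the venule adhesion molecule Madcam1 by 0.27, where the spread between probe sets was 0.22. Of those looked at before, Glycam1 differed by 2.02, Cxcl13 by 2.09 and Cr2, a complement receptor of B cells, by 1.41. Leukocytes infiltrating the gland itself would give the same values, and an effect of genotype stays open and untested.

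Keratinisation genes were lower in the knockout tumor. Fewer epithelial cells would lower luminal and basal genes too. The joint median of 29 of these was 0.11, which argues against that cause, but the test was chosen after the result was seen. Skin with hair follicles in the wild-type pool cannot be told apart from the rest. All 17 named hair follicle genes together had a median of -0.27, with Krt27 at -2.53, but 14 of them, Krt27 included, lay below the floor. Hair cortex keratins were far below it on both tumor arrays, Krt31 at signals of 21.5 and 7.0 and Krt35 at 19.3 and 14.2. The 3 measured genes had a median of -0.01 and went both ways, with Tchh at -2.51, Krt81 at -0.01 and Msx2 at 0.83. Krt81 passed the floor through the glands alone, and its tumor signals were 45.9 and 45.3. Their median, which is the value of Krt81, lies above the bound set in advance for excluding such skin. So dim a gene cannot bear on that bound, and 3 genes that disagree do not settle it. Krt25, the hair follicle keratin named above and not in this list, differed by -3.5, with signals of 293 and 1.1. Of 6 melanocyte genes, which skin with pigmented follicles would carry, 5 were below the floor, and their joint median was -0.01, with Mitf, the 1 measured, at -0.59, so they decide nothing. Less squamous differentiation in the knockout tumors may account for it, as other squamous genes had a median of -0.58, with 4 of 9 lower. Of these, Crct1 at -3.06, Lce3c at -2.76 and Klk8 at -1.09 were above the floor in the wild-type tumor alone, which favoured lower values in knockout. Ppl, at -1.18, was not. S100a14 went the other way, at 0.87. Over all 22 named squamous genes the median was -0.45, short of the bound of -0.5 set in advance, so the support is weak; skin without follicles in the wild-type pool would do the same and was not tested.

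Some genotype differences had opposite signs in gland and tumor, each at least 2-fold, and the difference between tissues was not tested. The tumor difference minus the gland difference was 7.65 for 2310057J18Rik, 7.66 for Car6 and 4.89 for Dcpp3, which were lower in the knockout gland and higher in the knockout tumor. In the tumors, however, 2310057J18Rik (signals 21.4 and 157) and Car6 (9.0 and 68.0) were below the floor on both arrays, so their sign there is not established. It was -4.16 for Lce1a1, -3.56 for Osr1, -3.25 for S100a8 and -3.67 for S100a9, which were higher in the knockout gland and lower in the knockout tumor. In the glands Lce1a1 (42.0 and 130) and Osr1 (44.8 and 125) were below the floor on both arrays. Of the lists, fibroblast and extracellular matrix (-0.78), macrophage and neutrophil (-0.80) and MHC class II genes (-0.83) went in opposite directions in the tissues, in each tissue beyond random lists, again untested.

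Among the 583 unnamed probe sets above the floor, which enter no comparison above, 6 were higher and 1 was lower in the knockout in both tissues. The unnamed probe set that was lower had the largest joint decrease of all probe sets. Its signals were 6371 and 1031 in the wild-type and knockout gland and 6611 and 182 in the wild-type and knockout tumor, and the smaller of its differences was -2.60. Of those that were higher in knockout, the 2 with the largest joint increase had smaller differences of 2.12 and 1.40.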

How the results depend on the processing

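The alternative that leaves out salivary and leukocyte genes was chosen after seeing the data. No paired analysis was possible because each group had 1 array, and for the same reason none could be left out. Of 134 recomputed counts 71 stayed within 1.5 times and 63 moved. Of 988 list medians, 757 moved by no more than the spread of the medians of matched random lists. Another 225 moved by more and 6 turned sign, which was counted only for lists outside the central range of random lists. Of 2006 named gene values, 1609 moved by no more than the spread between probe sets and 395 by more. Another 2 turned sign, counted only where the difference was at least 2-fold. Smaller ones turned too, such as that of Actb in the gland, to -0.30 without shared probe sets. The cause was not tested, except that a floor or threshold by construction leaves fewer or more genes.

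For knockout against wild-type gland, 92 higher became 44 with median centring, 53 with cyclic loess, 181 with an offset of 1, 20 with the pooled median as offset, 147 without a floor, 43 with a floor on the mean, 34 with the floor at the 75th percentile and 6 at 4-fold. The 21 lower became 34 with quantile normalization, 39 with median centring, 40 with an offset of 1, 34 without a floor, 8 with a floor on the mean, 11 without shared probe sets, 12 at 4-fold and 11 without salivary and leukocyte genes, when 66 were higher. The share of higher genes was 81.4% as deposited, 66.3% with quantile normalization (67 and 34), 53.0% with median centring (44 and 39) and 63.9% with cyclic loess (53 and 30). Median centring moved the median of all genes to -0.21 in this comparison, and to 0.10 and 0.31 for tumor against gland in wild type and knockout, and differences are to be read relative to that.

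For the tumors, 176 higher became 281 with an offset of 1, 62 with the pooled median as offset, 107 with a floor on the mean, 93 with the 75th percentile and 23 at 4-fold. The 161 lower became 77 with the pooled median as offset, 98, 81 and 45 with the latter 3. For wild-type tumor against gland, 1065 higher and 1374 lower became 671 and 813 with the pooled median as offset, 683 and 774 with the 75th percentile, and 326 and 472 at 4-fold. For knockout, 1023 and 1479 became 662 and 908, 671 and 773, and 287 and 545. Median centring gave 1696 higher (62.1% against 40.9% as deposited), and no floor gave 2286 lower.

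The 12 genes higher in both tissues became 7 with each of the 3 scalings, 40 with an offset of 1, 1 with the pooled median as offset, 5 with a floor on the mean, 4 with the 75th percentile and 1 at 4-fold. The 1 lower became 3, 2 and 2 with quantile normalization, median centring and cyclic loess, 7 with an offset of 1, and 0 with a floor on the mean or the 75th percentile. The 31 with a difference of differences toward higher became 63 with an offset of 1, 15 with the pooled median as offset, 13 with a floor on the mean, 17 without shared probe sets and 10 at the higher threshold. The 56 toward lower became 96, 15 and 23 with the former 3, 26 with the 75th percentile and 8 at the higher threshold.

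Of the lists outside the central range, medians that turned sign in the gland were the Ly6 family (0.12 without a floor) and, with median centring, TGF-beta and BMP (-0.039), basal (-0.10), interferon (-0.07) and immediate early genes (-0.012). The medians turned by centring stayed above the median of all genes, which centring had moved to -0.21. In the tumor, milk genes turned to -0.031 without shared probe sets, and Csn1s2a to -0.09, and to -0.41 for tumor against gland in knockout. Several medians inside the central range also turned sign. Cell cycle medians ranged from 0.33 to 0.78 in the gland and from 0.84 to 1.18 in the tumor, B cell medians in the gland from 0.93 to 1.42 and keratinisation medians in the tumor from -3.56 to -0.58.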

Other observations

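The list of other leukocyte genes, which was high in the knockout gland, went apart in the tumors. Its median genotype difference there was -0.16, with 5 of 15 members positive, but Ltb, a cytokine that organises lymphoid tissue, differed by 1.11 and Lsp1, an actin-binding protein of leukocytes, by 1.05. Other squamous genes were close between the glands, with a median of 0.20. At least 2-fold higher in tumor than in gland were 7 of 9 in wild type, against 3 of 9 in knockout. Klk8, Evpl, Crct1 and Lce3c reached the floor on the wild-type tumor array alone, so the filter itself favoured this contrast. Over all 22 named squamous genes the medians for tumor against gland were 0.52 in wild type and 0.07 in knockout.

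Genes next to the Sca-1 gene were examined for a shared lower level in knockout, which a targeted locus or flanking chromosome from another strain might give. The prediction was written before the values were seen, and the neighbours were taken from the order of genes in the reference annotation. The 10 nearest measured genes had a median difference of 0.03 in the gland, at percentile 55.5 of 8093 windows of 10 genes, and -0.12 in the tumor, at percentile 12.4. A joint shift of the neighbourhood was therefore not seen, though a median of 10 genes cannot show an effect limited to the nearest ones. Single neighbours went either way in both tissues. Nearest was Ly6d, at -0.90 in the gland and 0.21 in the tumor. Next came Lynx1, at -0.76 in the gland and -0.92 in the tumor, where it was below the floor. Jrk was at 0.46 and 0.83.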
